A study of Rattus norvegicus with 2 samples.

How the data were processed

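RNA sequencing was run on 2 samples of rat myometrial progenitor cells, 1 labelled VEH and 1 labelled DES. Per the labels, each sample pooled cells of 5 animals at passages 1 to 3. Per the labels' protocols, total RNA was isolated with a column kit and treated with DNase I, libraries were enriched by PCR, and single reads of 36 bp were made on a HiSeq2500. Per the submitters' processing notes, TopHat, FastQC, SAMtools, featureCounts and DESeq2 were used with the builds rn4 and rn5. Their versions, settings and order, and which build each step used, are not given in the sources used here. Whether counting used strand is not given in the sources used here either, so overlapping and antisense genes cannot be told apart.

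The 1 file used is the authors' deposited result table, with 17327 genes, of which 4106 are listed at 0. Per the file headers it holds the DESeq2 columns for the mean, the fold change, its standard error, the statistic and the p-values. The mean is a signal on a linear scale that the authors made by dividing read counts by each library's size factor and averaging over both libraries, per the file headers. The deposited fold change and its standard error are on a log2 scale, and the fold change is shrunken towards 0. The deposited statistic is a score, the fold change over its standard error. The p-value and adjusted p-value are the authors' own, deposited in the table. Neither the file headers nor the labels say which group is the numerator of the fold change, so results are given for a numerator and a denominator library.

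The planned rule of size needed a value per library, which the table does not give, so the reads were recovered from it. Each mean is a whole number of reads of 1 library times a step plus a whole number of the other library's reads times a second step. The steps gave size factors of 1.01 for the numerator and 0.991 for the denominator library. For 9307 genes (70.4%) only 1 pair of whole numbers met the printed mean within its rounding. For the other 3914 genes the pair was taken whose shrunken negative binomial fit, made with the deposited fold change, gave the deposited standard error. Where the deposited fold change was very small in size, the pair whose log2 ratio lay nearest to it, after allowing for shrinkage, was taken instead. In 3887 genes with 1 possible pair this fit missed the deposited standard error by at most 8.87e-07. The strength of the fit's shrinkage was set to meet these same standard errors, and genes with few reads or small deposited fold changes were left out. The recovery was tested on simulated data: it returned both read counts for 3974 of 3974 simulated genes drawn at the levels of this comparison. Their fold changes and standard errors were made with the same fit. Where several pairs were possible, the simulation therefore could not test whether that fit describes the deposited values. In the same simulation, 90 of 100 lists of 20 genes lay beyond the central 95% of random lists when moved by 0.6 (log2). Of unmoved lists, 3 of 100 did. The simulated ratios were independent between genes and spread less than those of these 2 libraries. These rates need not hold here. No gene with a mean of at least 20 and a ratio over 0.05 in size had a deposited fold change of the opposite sign. For the 3914 genes the choice of pair used the deposited fold change, so there this is no independent check.

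Reads were divided by the size factors, and log2 ratios used a pseudocount of 1 normalised read. A gene was counted as higher or lower when the ratio was at least 2-fold, the mean at least 20 and a 95% counting interval of the ratio excluded 1. The interval is the exact Clopper-Pearson interval of the share of reads, given their sum. Folds in the text use no pseudocount. Where 1 library had 0 reads, the fold is a lower bound against a floor of 3 reads in that library. Reads without molecular identifiers are not independent molecules, so these intervals and floors cover counting error only. With 106599579 and 104793348 reads in the listed genes, counting error is small for most genes. The spread between animals or cultures cannot be estimated from 1 library per group, so no test was run and no p-value was computed.

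The 39 pathway lists and 12 cell type lists, the rule of size, the rule for naming genes and all but the added alternatives were fixed before the data were examined. Of 894 list symbols, 759 were found as written and 8 through names in RefSeq's GRCr8 annotation; 127 had no value above 0, of which 59 are listed at 0. A list's median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. Lists with under 4 members above the minimum got no percentile. Setting genes unread in 1 library at the floor moved these medians by at most 0.10. Genes were named when among the 10 largest or 10 smallest ratios, the 5 most abundant of a library, the 4 most changed members of a list or the repair genes beyond 2-fold. Another 14 genes, from Esr1 to Med12, were to be named whatever their values. Some genes that these rules take are not reported here. Symbols of unnamed loci were passed over, 2 of them among the largest and smallest ratios. Gene names converted to dates by a spreadsheet stood in 23 rows above 0 and were counted but not named. RefSeq was used for names and gene order; its positions are of another build and are not given.

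The alternatives were total count, TMM and upper-quartile scaling, pseudocounts of 0.5 and 5, no minimum and a minimum of 100, 1.5-fold and 4-fold limits, and other counting intervals. For lists they were also the mean of members, 10 bins and no matching. After the data were seen, the authors' deposited fold change in place of the recovered ratio and leaving out chromosomes 4 and 7 were added. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.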

Results

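The transcriptome of rat myometrial progenitor cells, cultured precursor cells of the smooth muscle layer of the uterus, was sequenced in 2 groups. The groups were cells labelled VEH-exposed and cells labelled DES-exposed. In studies of developmental exposure these abbreviations commonly stand for the vehicle and for the synthetic estrogen diethylstilbestrol. Each group had 1 library (n = 1), made from pooled cells of 5 animals at passages 1 to 3. The comparison asks how gene expression differs between exposed and unexposed cells.

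Values come from the authors' deposited table of fold changes, from whose means the read counts of both libraries were recovered for all 13221 genes above 0. The table does not state which group is the numerator of its fold change, and the values cannot settle it. The libraries are therefore called the numerator library, whose reads raise the deposited fold change, and the denominator library, and no direction below can be read as an effect of DES. The numerator library held 106599579 reads in these genes and the denominator library 104793348, a ratio of 1.02. Reads outside the listed genes are not known. With 1 library per group, no difference below has a replicate check. Intervals are 95%. Those of ratios, like floors, cover counting error only. Those of medians come from the ranked values of the genes, taken as independent.

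Of 11212 genes with a mean of at least 20 normalised reads, 1560 were at least 2-fold higher and 1429 at least 2-fold lower in the numerator library. These are 13.9% and 12.7% of the genes. The median log2 ratio over all 11212 genes was 0.01. At 8-fold or more, 574 genes were higher and 285 lower. Among genes with this mean, 160 had reads in the numerator library only and 21 in the denominator library only.

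With the pseudocount of 1, the gene with the largest ratio was Efemp1, which encodes the matrix protein fibulin-3. It had 136540 reads in the numerator library and 0 in the denominator library, so it was at least 44699-fold higher against a floor of 3 reads per library. Angpt2, the vascular ligand angiopoietin-2, had 188530 and 3 reads, a ratio of 61718 with an interval of 21119 to 299281. Fam84a had 10686 and 0 reads (at least 3498-fold higher), and Sprr1a, a cornified envelope protein, had 5790 and 0 (at least 1895-fold). Adra2a, an adrenergic receptor, was at least 1611-fold higher, S100g, the vitamin D-dependent calcium-binding protein calbindin-D9k, at least 1447-fold, Cnr1, a cannabinoid receptor, at least 1273-fold and Kprp at least 997-fold. All 4 had 0 reads in the denominator library. Thbs2, encoding thrombospondin-2, had 70502 and 20 reads (3462-fold, interval 2241 to 5668). Serpinb2, encoding plasminogen activator inhibitor-2, had 6454 reads and 1 read (6338-fold, interval 1137 to 250395).

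At the other end stood Abcc9, the sulfonylurea receptor subunit of ATP-sensitive potassium channels, with 38 reads in the numerator library and 168646 in the denominator library (4519-fold lower, interval 3292 to 6386). Kcnj8, the pore subunit of the same channels, had 6 and 5457 reads (926-fold lower, interval 425 to 2525). Was, a regulator of actin in blood cells, had 0 and 4194 reads (at least 1423-fold lower). Cdh5, encoding the endothelial cadherin, had 2 reads in the numerator library (1103-fold lower, interval 305 to 9111). The developmental transcription factor Sim2 had 3 and 3985 reads (1353-fold lower, interval 462 to 6561). The homeobox genes Hmx2 and En2 had 0 reads in the numerator library against 698 and 653, and were at least 237-fold and 222-fold lower. Tril had 15 and 16250 reads (1103-fold lower) and the adhesion molecule Cntn2 had 57 and 33227 (594-fold lower). Cml5 had 0 and 1103 reads (at least 374-fold lower); it has close relatives, with which reads may be shared, and is uncertain.

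**Figure D1:**
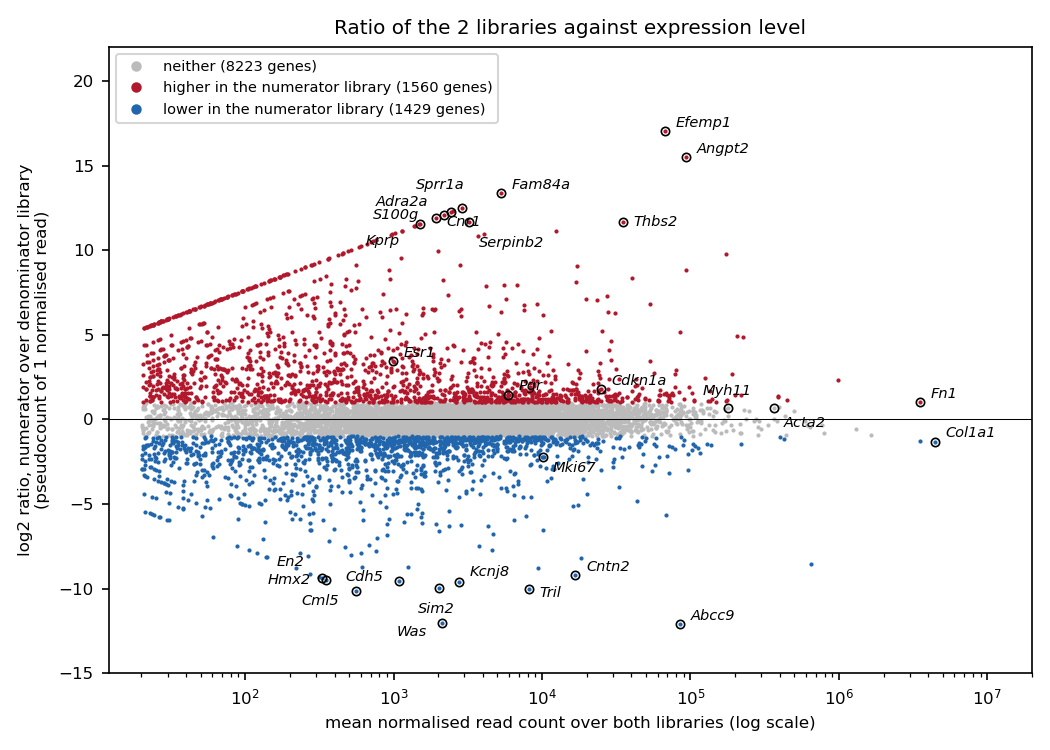
Log2 ratio of the numerator over the denominator library (vertical axis, pseudocount of 1 normalised read) against the mean normalised read count over both libraries (horizontal axis, log scale), 1 point per gene with a mean of at least 20. The 1560 genes higher and 1429 genes lower by the rule of size are coloured, and named genes are circled, from Efemp1 at 17.05 to Abcc9 at -12.10.

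The most abundant transcripts encoded matrix proteins. Fn1 (fibronectin) led the numerator library with 4776490 reads and was 2.02-fold higher there. Col1a1 (type I collagen) led the denominator library with 6284823 reads and was 2.48-fold lower in the numerator library. Col1a2 was 2.45-fold lower. Thbs1 (thrombospondin-1) was 5.02-fold higher. Sparc was 1.92-fold and Col3a1 1.47-fold lower, within the 2-fold limit.

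Gene lists fixed before the data were examined were described by the median log2 ratio of their members and by its percentile among 10000 random lists matched on expression. Of 47 lists with at least 4 members above the minimum, 11 lay above and 12 below the central 95% of random lists. If genes varied independently, 2.35 lists would lie beyond it. Members of a list may vary together between any 2 cultures, so more lists could lie beyond it without an effect of the group. Lists share members, so these counts are not of independent results.

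Single steroid receptor genes lay beyond 2-fold, while their list as a whole lay within the random lists. Esr1, estrogen receptor alpha, had 1824 and 165 reads (10.9-fold higher in the numerator library, interval 9.25 to 12.8). The progesterone receptor gene Pgr had 8766 and 3102 (2.78-fold higher, interval 2.66 to 2.89). Gper1, a membrane estrogen receptor, had 1 and 49 reads (49.9-fold lower, interval 8.55 to 2010). Esr2, estrogen receptor beta, had 0 and 3 reads, at the floor in both libraries. The list of steroid receptors and coregulators as a whole had 3 of 15 members higher and 1 lower, with a median of -0.05 at the 38.2 percentile. Estrogen-responsive uterine genes also lay within the random lists (median 0.28, 71.4 percentile), with 5 of 13 members higher. These included Oxtr, the oxytocin receptor gene, with 66 and 0 reads (at least 21.6-fold higher), Igf1 (7.07-fold) and the growth factor gene Areg (log2 ratio 1.96); Gja1, encoding the gap junction protein connexin 43, was 2.98-fold lower. This list's median turned to -0.51 at the 1.36 percentile without genes of chromosomes 4 and 7, and to -0.37 at the 5.62 percentile with a minimum of 100.

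Uterine genes reported as reprogrammed in rat models of developmental exposure had a median of 5.89, at the 99.99 percentile, with 5 of 7 members higher and 2 lower. Beside S100g, Dio2 (a thyroid hormone deiodinase) had 435 and 0 reads and was at least 142-fold higher. The protease gene Mmp3 was 115-fold higher (interval 108 to 123) and Pdlim3, an actin-associated protein, 63.6-fold higher (interval 37.7 to 117). The 2 lower members were Nr2f2 and, named after its value was seen, Car8 (61 and 1364 reads).

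Contractile smooth muscle genes had a median of 0.62, at the 99.4 percentile; by the mean of members this percentile was 83.4. Of its 19 members, 3 were at least 2-fold higher and 3 lower. Acta2 (smooth muscle actin, 1.57-fold higher) and Myh11 (smooth muscle myosin, 1.61-fold higher) stayed within the limit. Synm, an intermediate filament protein, was 90.2-fold higher (interval 77.3 to 106). Kcnmb1, a potassium channel subunit, was 5.68-fold lower, Mylk (myosin light chain kinase) 4.05-fold lower and Itga8 2.67-fold lower. Mesenchymal stem and progenitor markers split, with 6 of 17 higher and 7 lower (median 0.32, 91.0 percentile; -0.25 and 2.02 without chromosomes 4 and 7, and -0.25 and 6.86 with a minimum of 100). Vcam1 had 4327 and 13 reads (327-fold higher, interval 191 to 614), Nt5e was 6.30-fold higher and Cd34 had 54 and 3 reads (17.7-fold higher, interval 5.74 to 88.4). Kit was 17.1-fold lower. Cd44 was 1.43-fold higher, within the limit.

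Among markers of other cell types, the pericyte, endothelial, fibroblast, endometrial stromal and macrophage lists lay below the random lists, and none lay above them. Pericyte markers had a median of -2.19, below every random list, with 5 of 7 lower and 1 higher. Beside Abcc9 and Kcnj8, the receptor gene Notch3 was 92.1-fold lower (interval 80.6 to 106) and Mcam 4.57-fold lower. Without genes of chromosomes 4 and 7, which leaves 4 members without Abcc9 and Kcnj8, the median was -0.73 at the 2.56 percentile. Endothelial markers had a median of -2.14, below every random list, with 5 of 8 lower. Esam was 77.9-fold lower and Pecam1 8.75-fold lower, while Tek, the receptor of the angiopoietins, was 8.11-fold higher. Fibroblast markers were split into 5 higher and 6 lower of 11 (median -1.10, 0.32 percentile), but the mean of members was 0.90 and the median without chromosomes 4 and 7 was 0.17. Tcf21, a mesenchymal transcription factor, had 394 and 0 reads (at least 129-fold higher) and Fap was 6.80-fold higher. Endometrial stromal markers had a median of -0.71 at the 0.63 percentile (11.97 by the mean of members); 4 of 10 were lower, including Mme at 6.40-fold and Nr2f2 at 3.77-fold, and Prl8a2 was 5.33-fold higher.

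Macrophage markers had 4 members above the minimum, 2 of them lower (median -2.07, 1.46 percentile). Csf1r was 12.5-fold and Lyz2 14.7-fold lower, on 22 and 5 reads in the numerator library, and Cd68 was 4.93-fold higher. The percentile was 17.4 with no minimum, 7.38 by the mean of members and 3.43 by the authors' deposited fold change. Epithelial markers (median 1.49, 91.6 percentile, 3 of 6 higher and 1 lower), mesothelial markers (-0.10, 43.2, 2 of 6 higher and 2 lower), neural markers (0.40, 73.3, 1 of 5 higher) and skeletal or cardiac muscle markers (-0.11, 37.7, 3 of 7 higher and 2 lower) lay within the random lists. Without matching, epithelial markers lay at the 99.5 percentile. Mesothelial markers, with a median of 0.76, lay at the 98.96 percentile with a minimum of 100 and, with a median of -0.97, at the 1.51 percentile without chromosomes 4 and 7. Among these lists the keratin gene Krt18 was 8.90-fold higher, Upk1b 23.5-fold higher, Msln (mesothelin) 5.33-fold lower, Ncam1 2.73-fold higher, Tnnt3 (a skeletal troponin) 9.48-fold lower and Acta1 (skeletal actin) 6.12-fold higher. Lists with under 4 members above the minimum got no percentile: lymphocyte markers had 1 of 2 higher and 1 lower (median -1.63), adipocyte markers 2 of 3 lower and 0 higher (-3.13) and erythroid markers 3 of 3 higher (5.79, or 4.17 with unread genes at the floor). With no minimum, the lymphocyte median turned to 1.07 (64.9 percentile, 4 members) and the adipocyte median was -2.33 (0.245 percentile, 7 members). Lpl, lipoprotein lipase, had 41 and 7391 reads (184-fold lower). The globin genes Hba1 and Hba2, near-identical copies whose reads cannot be told apart with certainty, had 82 and 55 reads in the numerator library and 0 in the denominator library.

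Cell cycle genes were lower in the numerator library. Their median was -1.53, below every random list, with 21 of 31 members lower and 2 higher. Mki67, the proliferation marker Ki-67, was 4.73-fold lower (interval 4.56 to 4.91), Nusap1 6.07-fold, Kif2c 5.32-fold and Top2a (topoisomerase II alpha) 4.96-fold lower. The 2 higher members, named after their values were seen, were Tyms and Ccne1, at log2 ratios of 1.41 and 1.05. Replication-dependent histone genes had 3 of 5 members higher, 0 lower and a median of 1.16, within the central 95% of random lists and beyond it, at the 98.8 percentile, without matching. Hist1h2bh was 3.07-fold higher, but members of this family are near-identical and uncertain. p53 target genes had a median of 0.61 at the 99.7 percentile (93.7 by the mean of members), with 6 of 16 higher. Cdkn1a, the cell cycle inhibitor p21, was 3.42-fold higher (interval 3.35 to 3.50), Btg2 5.47-fold, Plk3 3.96-fold and Ccng1 3.72-fold; the 1 lower member, Gadd45a, was named after its value was seen (-1.15). Senescence-associated genes lay within the random lists (median 0.30, 92.5 percentile; 98.0 by the mean of members), with 6 of 17 higher, among them Igfbp5 with 507 and 2 reads (249-fold, interval 68.6 to 2061), and 4 lower, among them Igfbp7 (6.69-fold).

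The homologous recombination list had a median of -0.55 at the 1.90 percentile, with 5 of 22 members lower and 0 higher. Bard1 was 5.51-fold, Brca2 3.31-fold, Rad52 3.05-fold, Palb2 2.48-fold and Xrcc2 2.34-fold lower. Brca1 (1.77-fold lower), Rad50 (1.23-fold lower), Nbn (1.06-fold lower) and Mre11a (1.01-fold lower) stayed within the limit. The percentile moved to 3.43 with no minimum, 8.22 with a minimum of 100, 2.98 by the mean of members and 2.63 without chromosomes 4 and 7. Fanconi anemia genes (-0.49, 17.7 percentile), mismatch repair (-0.39, 12.8), the damage checkpoint (-0.31, 18.6), base excision (-0.20, 22.7), end joining (-0.15, 34.6) and nucleotide excision (0.16, 82.5) lay within the random lists. Members beyond 2-fold were Ube2t (5.69-fold lower), Fancd2 (3.25-fold lower), Neil3 (5.25-fold lower), Mutyh (2.31-fold lower), Nhej1 (3.19-fold lower), Xpa (2.44-fold lower), Ddb2 (2.16-fold lower) and Xpc (2.14-fold lower). Xrcc5, encoding the end-joining protein Ku80, was 2.24-fold higher. None of the 15 mismatch repair or 12 checkpoint members passed 2-fold; the most changed were Mlh3 (1.86-fold lower) and Mdc1 (1.86-fold higher).

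Matrix genes split without a common direction: 10 of 26 fibrillar collagen and matrix genes were higher and 5 lower (median -0.19, 3.39 percentile). A minimum of 100 moved this percentile to 1.21, while the mean of members was 0.88 at the 95.5 percentile. Col11a1 was 452-fold higher (interval 411 to 499), Mfap5 6.65-fold and Col6a2 6.41-fold higher. Matrix proteases and inhibitors had 7 of 21 higher and 7 lower (median -0.13, 13.9 percentile; mean of members 0.68, 90.8 percentile). Mmp10 was 284-fold, Mmp13 170-fold and Adamts1 30.1-fold higher.

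Growth factor genes had a median of 0.78, above every random list, with 13 of 27 higher and 6 lower. Ereg (epiregulin) had 512 and 0 reads and was at least 168-fold higher, Fgf7 was 83.9-fold higher, and Igfbp2 had 231 reads and 1 read (227-fold, interval 40.3 to 8999). TGF-beta and BMP genes had a median of 0.49 at the 99.3 percentile (97.1 with a minimum of 100), with 10 of 26 higher and 1 lower. The BMP antagonists Grem1 and Nog stood out in size: Grem1 had 348859 and 388 reads (883-fold higher, interval 799 to 978) and Nog 629 and 0 (at least 206-fold). Inhbb had 283 reads and 1 read (278-fold higher, interval 49.5 to 11016) and Bmp4 63 and 2 (30.9-fold, interval 8.22 to 261). Wnt genes had a median of -0.46 at the 0.60 percentile, with 5 of 24 higher and 7 lower; the percentile was 18.1 with no minimum, 5.38 with a minimum of 100, 48.0 by the mean of members and 10.3 without chromosomes 4 and 7. The secreted Wnt modulators Sfrp2 (222 and 0 reads, at least 72.7-fold higher), Rspo1 (33.6-fold higher) and Sfrp1 (18.9-fold lower), and Nkd1 (16.9-fold lower), changed most. Hox and Mullerian duct patterning genes had a median of -0.95 at the 0.05 percentile (2.65 by the mean of members), with 7 of 15 lower and 2 higher. Emx2 was 8.29-fold lower, Hoxb5 5.43-fold and Hoxb7 4.64-fold lower, and Hoxa13 4.11-fold higher.

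Inflammatory cytokine and chemokine genes were the highest of the immune lists: the median was 3.55, above every random list, and 9 of 13 members were higher and 0 lower. Ccl7 was 322-fold (interval 285 to 367), Cxcl12 136-fold, Ccl2 113-fold and Ptgs2 (cyclooxygenase-2) 35.2-fold higher. Complement genes had a median of 1.59 at the 99.9 percentile, with 8 of 12 higher and 2 lower. Cfi was 54.5-fold and Serping1 16.3-fold higher. Interferon-stimulated genes lay within the random lists (median -0.03, 46.7 percentile), with 5 of 21 higher and 0 lower, including Cxcl10 (11.2-fold) and Ifit1 with 237 reads and 1 read (233-fold, interval 41.4 to 9232). Immediate early genes, induced within minutes of a stimulus, had a median of 1.16, above every random list, with 11 of 18 higher and 0 lower. Egr3 was 6.41-fold, Nr4a1 5.99-fold and Egr2 4.18-fold higher.

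Xenobiotic metabolism genes had a median of 1.60, above every random list, with 8 of 14 higher and 2 lower. Aldh3a1 was 21.5-fold and Ahrr, the aryl hydrocarbon receptor repressor, 7.19-fold higher. Gsta1 was 14.7-fold and Gsta3 20.5-fold higher, but they belong to a family of close copies and are uncertain. NRF2 antioxidant genes lay within the random lists (0.11, 54.6 percentile; 4 of 20 higher and 2 lower), with Nqo1 4.86-fold higher and the metallothioneins Mt2A and Mt1a, also close copies, 7.84-fold and 7.73-fold lower. Heat shock genes had a median of 0.55 at the 98.8 percentile (93.9 by the mean of members), with 4 of 14 higher, led by Cryab (10.8-fold), and 1 lower. Unfolded protein response genes (-0.11, 14.0 percentile; 1 of 19 higher and 2 lower) included Ddit3 at 5.28-fold lower and Atf3 at 3.35-fold higher.

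Cholesterol synthesis genes were higher together. The median was 1.41, above every random list, and 15 of 21 members were higher and 0 lower. Fdps was 4.51-fold (interval 4.39 to 4.65), Idi1 4.41-fold and Lss 4.37-fold higher. Fatty acid genes lay within the random lists (0.23, 83.5 percentile), with 3 of 14 higher and 3 lower. Without chromosomes 4 and 7 the percentile was 97.8. Scd1, stearoyl-CoA desaturase, was 17.5-fold and Elovl6 5.68-fold higher, while Lpl, lipoprotein lipase, was 184-fold lower. Glycolysis and hypoxia genes had a median of -0.49 at the 0.03 percentile (4.55 without chromosomes 4 and 7), with 7 of 24 lower and 2 higher. Ndrg1 was 15.9-fold, Adm (adrenomedullin) 7.74-fold, Egln3 3.97-fold and Hk2 3.56-fold lower. Oxidative phosphorylation genes had 0 of 33 members beyond 2-fold (median 0.08, 52.5 percentile). Cytosolic ribosomal protein genes also had 0 of 35 beyond 2-fold, yet their median was -0.33 at the 0.08 percentile. Reference genes had a median of 0.02 (38.7 percentile), but 4 of 14 were higher, including Ppia at 2.16-fold and Actb, encoding beta-actin, at a log2 ratio of 1.32.

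DNA methylation and Polycomb genes had a median of -0.51 at the 0.93 percentile (8.15 by the mean of members), with 3 of 14 lower: Dnmt3a (2.77-fold), Kdm6b (2.20-fold) and Dnmt3b (2.16-fold). Genes altered in uterine fibroids had a median of -0.02 at the 43.5 percentile, with 1 of 10 lower. Med12, the gene most often mutated in human fibroids, had 6072 and 5973 reads (log2 ratio -0.00, interval of the ratio 0.963 to 1.03). Plag1 was 2.87-fold lower. The pluripotency list had 2 members above the minimum, Klf2 (2.64-fold higher) and Klf4 (2.42-fold higher).

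**Figure D2:**
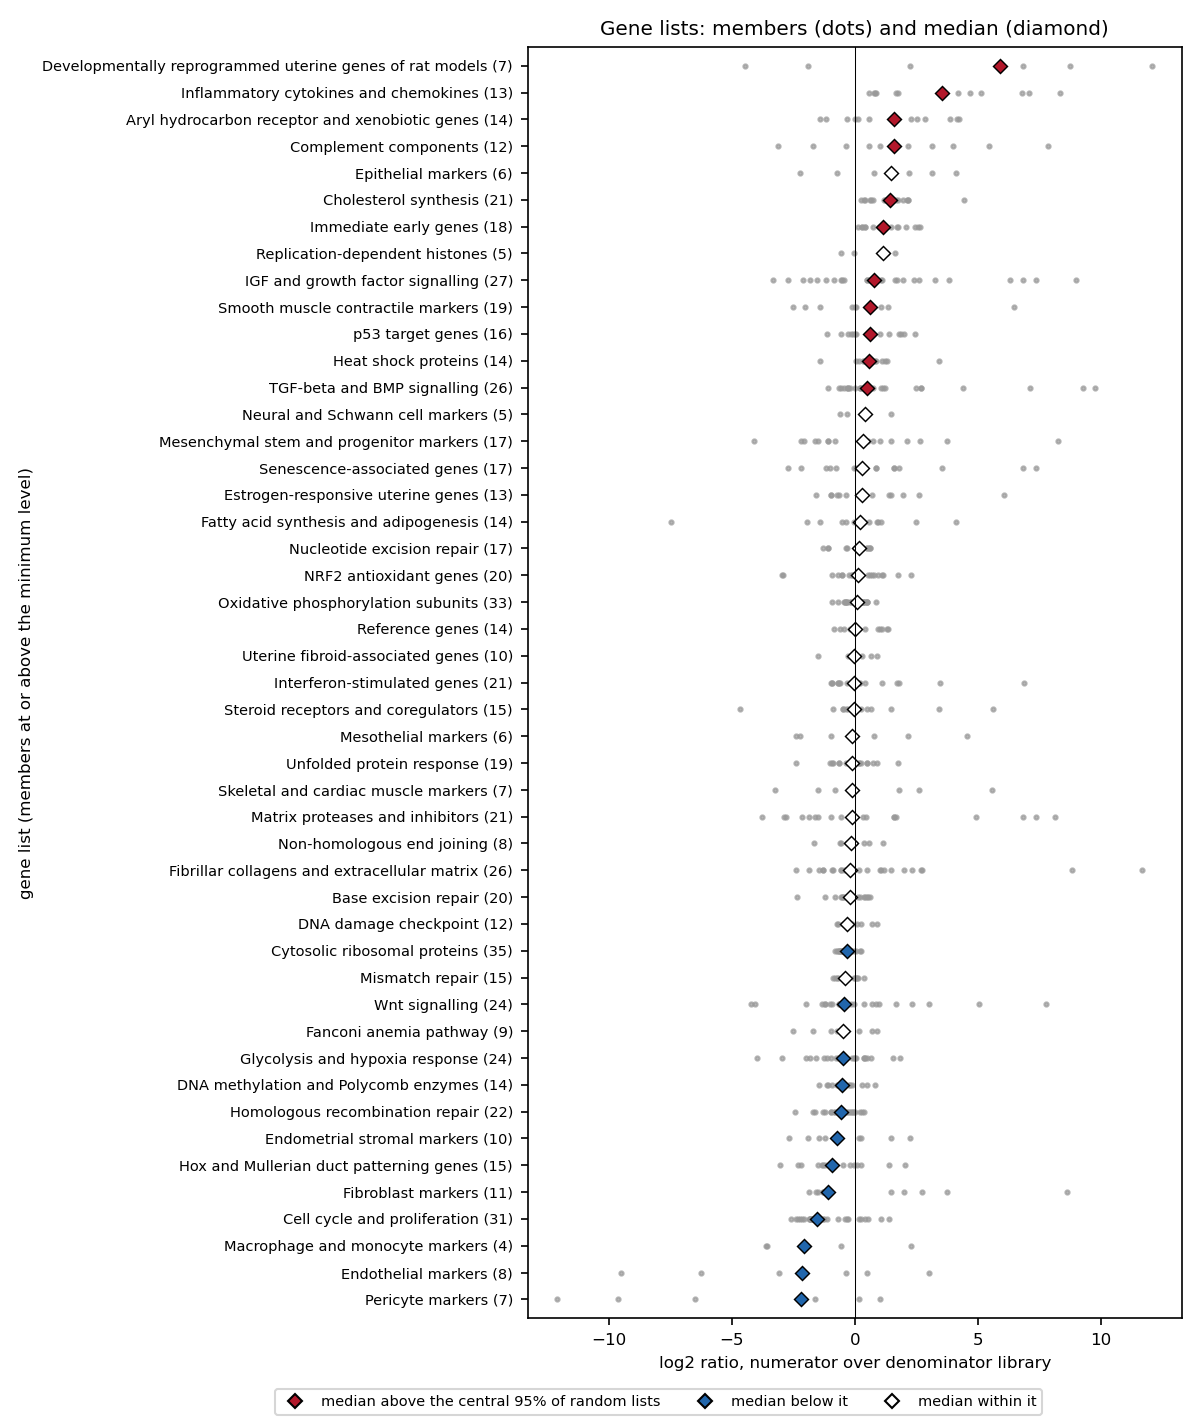
Log2 ratio of the numerator over the denominator library (horizontal axis) for the members (dots) of 47 gene lists, with each list's median (diamond) coloured by its place among 10000 random lists matched on expression. Medians run from -2.19 for pericyte markers to 5.89 for reprogrammed uterine genes, with 11 lists above and 12 below the central 95%.

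Ratios also differed by chromosome. With genes grouped and ordered by RefSeq's GRCr8 annotation, which placed 98.2% of the genes above the minimum, the 729 genes of chromosome 7 had a median log2 ratio of -0.57 (interval of the median -0.63 to -0.50). The 617 genes of chromosome 4 had a median of -0.38 (interval -0.44 to -0.30). The medians of the other chromosomes lay between -0.06 and 0.26, the highest that of chromosome 13 (interval 0.14 to 0.36). On chromosome 1, 9 successive windows of 30 genes, from Il4r to Cdca5 (the window ends, named after their values were seen), had medians between -1.02 and -0.45. These comparisons were chosen after the data were seen, and genes are not independent replicates.

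**Figure D3:**
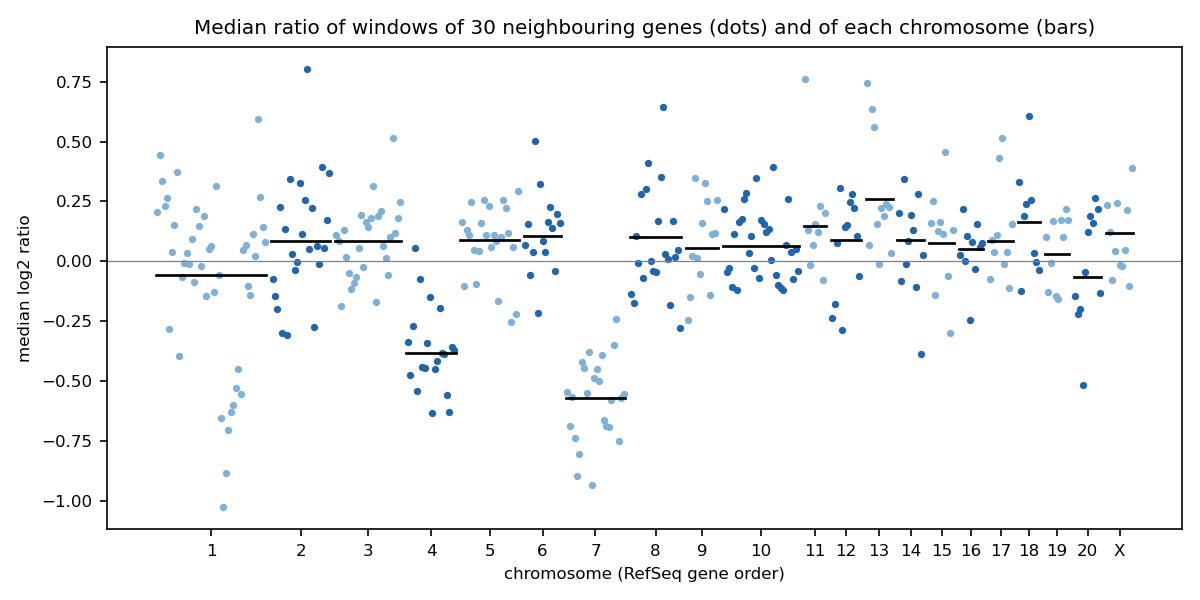
Median log2 ratio of the numerator over the denominator library (vertical axis) in windows of 30 neighbouring genes (dots) along each chromosome (horizontal axis, RefSeq gene order), with the median of each chromosome as a black bar. The windows of chromosome 7 lie between -0.93 and -0.24, and 9 successive windows of chromosome 1 lie between -1.02 and -0.45.

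The authors' deposited table, made with DESeq2 per the submitters' processing notes, called 0 of 13221 genes at an adjusted p under 0.05. Its smallest adjusted p was 0.999. An unadjusted p under 0.05 was given by the authors' deposited table to 427 genes, 248 with a positive and 179 with a negative fold change, where 661 of 13221 would be 5%. With 1 library per group these p-values cannot rest on replicates. The deposited log2 fold changes were smaller than the recovered ratios and reached at most 3.37 in size. Among genes with a mean of at least 20, the authors' deposited fold change was at least 2-fold positive in 1177 and negative in 1096. Of the 2989 genes beyond 2-fold by recovered reads, 716 (24.0%) had a deposited size under 1. For Efemp1 the authors' deposited table gave a log2 fold change of 0.43, against a recovered log2 ratio of at least 15.45 with the floor of 3 reads.

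**Figure D4:**
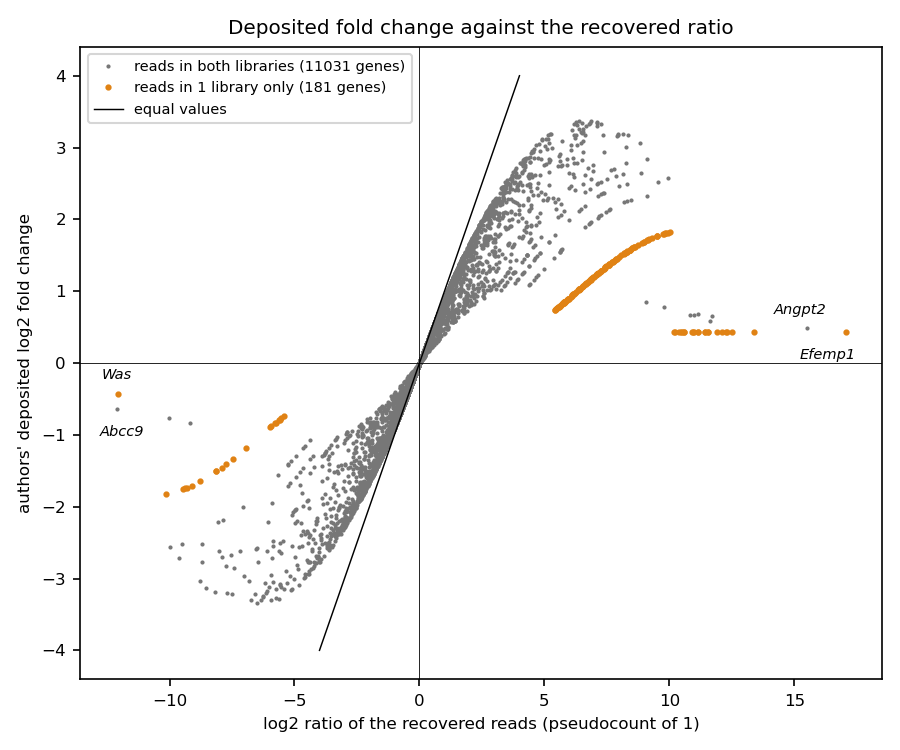
The authors' deposited log2 fold change (vertical axis) against the log2 ratio of the recovered reads with a pseudocount of 1 (horizontal axis), 1 point per gene with a mean of at least 20. The deposited values peak at 3.37 in size and return to 0.43 for Efemp1 and other genes with many reads in 1 library only (orange).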

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

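The alternatives that left out chromosomes 4 and 7 or used the authors' deposited fold change were chosen after the data were seen. Leaving out chromosomes 4 and 7 kept the low run of windows on chromosome 1. The counts of 1560 higher and 1429 lower genes stayed within 1.5 times under every scaling, pseudocount, minimum and counting interval tried, and under both added alternatives. They depended on the fold limit: 2534 and 2553 genes at 1.5-fold, and 838 and 573 at 4-fold. Upper-quartile scaling gave 1509 and 1501. The authors' table gave 0 calls at each threshold tried. The mean of members in place of the median left 5 lists below the central 95% of random lists, in place of 12. Of the lists beyond the central 95%, it turned the sign for Wnt signalling (0.16) and fibroblast markers (0.90), whose members go both ways; fibroblast markers also turned without chromosomes 4 and 7 (0.17). Of the lists within the central 95%, 8 turned with the mean of members: fibrillar collagens and matrix (0.88), matrix proteases (0.68), skeletal or cardiac muscle (0.62), interferon-stimulated (0.45), mesothelial (0.31), steroid receptors (0.30), nucleotide excision (-0.02) and fatty acid genes (-0.09). Without chromosomes 4 and 7, 4 turned: mesenchymal (-0.25), estrogen-responsive (-0.51), unfolded protein response (0.03) and end joining genes (0.01). With a minimum of 100, 3 turned: mesenchymal (-0.25), estrogen-responsive (-0.37) and mesothelial (0.76). With no minimum, 2 turned: mesothelial (0.76) and interferon-stimulated genes (0.02). Of the 23 lists beyond the central 95%, all 23 stayed there under total count and TMM scaling, both pseudocounts, 10 bins and no matching, 22 under the deposited fold change, 20 with no minimum, 19 with a minimum of 100 (which leaves too few macrophage markers), 17 without chromosomes 4 and 7 and 13 by the mean of members. Of the other lists, 4 came to lie beyond the central 95% without chromosomes 4 and 7, 2 with a minimum of 100, 2 with no matching and 1 by the mean of members; with no minimum, adipocyte markers got a percentile and lay below (0.245), and the lymphocyte median turned to 1.07. Under total count and TMM scaling and both pseudocounts, 0 of 222 named genes passed 2-fold and changed direction; TMM scaling moved 5 and a pseudocount of 5 moved 25 beyond their counting interval. Apart from the settings' own construction, the cause of these changes was not tested. Depth limits only genes with few reads; the lack of a second library per group limits every result.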

Other observations

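The tests of matched genes on chromosome 7 and of chromosome 7 without strongly changed genes were set before their results were seen; the gene group of the next paragraph and the other tests were chosen after seeing the data.

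Imprinted genes, expressed from the copy of 1 parent, differed between the libraries in both directions: of 17 such genes above the minimum, 4 were higher and 6 lower in the numerator library. H19 had 0 and 275 reads (at least 93.3-fold lower), Plagl1 3 and 1027 (349-fold lower, interval 119 to 1693) and the growth inhibitor Cdkn1c 17 and 299 (17.9-fold lower). The largest of the 4 higher entries, RGD1566401, to which Meg3 was matched through RefSeq names, had 556 and 0 reads (at least 182-fold higher). Ndn was 12.9-fold, Dio3 8.75-fold and Nnat 6.38-fold higher.

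Genes of chromosomes 7 and 4 were lower together in the numerator library. Against genes matched on level and length chromosome 7 still lay at -0.58, which argues against level or length as the whole cause. Without genes beyond 2-fold it lay at -0.44. A few strongly changed genes could hardly move a median of 729 genes, so that test could not have found them as the cause. On chromosome 7 100% and on chromosome 4 95% of windows of 30 genes lay below the median of all genes, against 34.4% on the other chromosomes, and on chromosome 1 a run of 9 windows lay below -0.4, where 1000 shuffles of the ratios over genes gave runs of at most 2. A hypothesis is that the cultures differ in copy number, since 3 copies against 2 would give 0.58 on the log2 scale. This may be an extra chromosome 7, and chromosome 4 in part of the cells, in the denominator library. It may also be a loss in part of the cells of the numerator library. Each library pooled cells of 5 animals, so 1 extra copy would give 0.58 only if nearly all cells of the pool carried it. Chromosome 13 lay the other way, with a median of 0.26 and 9.1% of its windows below the median of all genes. The 9 windows of the run on chromosome 1 had a median of -0.63. The lowest reached -1.02, beyond what 3 copies against 2 give, as did the lowest window of chromosome 7, at -0.93. DNA, which would decide on copy number, was not analysed here. Whether such a difference would be chance in culture, a property of the animals or tied to exposure cannot be settled with 1 library per group.

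Genes with nearly all reads in 1 library had small deposited fold changes: of 26 genes with reads in 1 library only and a mean of at least 500, 24 had a deposited size under 0.5, although the recovered log2 ratios of the 26 were at least 8.41 in size with the floor of 3 reads. Wrong splitting of the means is argued against by 21 of these genes, whose mean allows only 1 split. The dispersion implied by the deposited values was computed for the 34 genes at 10 or more on the recovered log2 scale (pseudocount of 1). It was 67.6 times higher there than in all genes (median 0.148). It is solved from the recovered reads and the deposited fold changes, so this gap restates the pattern. Its median was 9.999 in the 34 genes, and 9.999 in the groups at 10 to 11, 11 to 12, 12 to 13 and 13 to 14. The 1 gene at 15 to 16 had 8.889. Such a near-constant value would follow from a ceiling on the dispersion, estimated across both libraries, followed by shrinkage towards 0. Efemp1, Angpt2 and Abcc9, among the most unequal genes by recovered reads, had deposited log2 fold changes of 0.43, 0.48 and -0.63.

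The homologous recombination list, below the random lists but within them under 4 alternatives, stood beside lower cell cycle genes; the Fanconi list lay within the random lists. The repair lists tied to DNA replication (homologous recombination, Fanconi and mismatch repair, 45 genes) had a pooled median of -0.50, and nucleotide excision, base excision and end joining (45 genes) one of 0.01, a gap of 0.51. This split was chosen after the list medians were seen and leaves out the damage checkpoint list (median -0.31), so the gap is no independent test. Fewer cycling cells in the numerator library may lower such genes. Of 31 cell cycle genes 21 were lower, and the 2 higher were Tyms and Ccne1. Replication-dependent histones also went the other way (median 1.16, 3 of 5 higher). Their list lay within the random lists, and its near-identical members are uncertain. The values do not decide whether fewer cycling cells lowered the repair genes. A separate change of repair genes, tied to exposure or not, was not tested.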
